A study of Nannospalax galili and Spalax carmeli with 2 samples.

How the data were processed

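The data are RNA-seq measurements of 2 placenta samples, 1 of Spalax galili (listed under the synonym Nannospalax galili) and 1 of Spalax carmeli. The species came from the organism label. Per the labels' protocols, the villous portion was homogenised, total RNA was extracted and treated with DNase, and standard Illumina libraries were made. RSEM was used, per the submitters' processing notes, and its version is not given in the sources used here. Neither the assembler, the sequencing layout nor the way contigs were matched to mouse genes is given in the sources used here.

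The expected counts per contig were deposited by the authors without normalization, per the file headers, in the column layout of RSEM. The TPM values were deposited beside them, per the file headers, and summed to 999985 in S. galili and 1000008 in S. carmeli after repeated rows were dropped. They were recorded as an unspecified unit in the unit check because contigs listed on 2 rows raise the sum over all rows by 5.78% in S. galili and 2.67% in S. carmeli. The contig sets of the 2 files are separate. A contig with both a cDNA and a non-coding match appeared on 2 rows with equal values (958 contigs in S. galili and 1162 in S. carmeli), and its cDNA row was kept. A lookup column unrelated to the row it stands in was not used.

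Unnamed contigs held 22.7% of TPM and 8.00% of expected counts in S. galili, and 40.3% of TPM and 20.6% of expected counts in S. carmeli. They entered the library totals and the shares of the most abundant genes but no ratio. Contigs with the same mouse Ensembl gene identifier were summed, and genes were joined between libraries by that identifier, because the names of 19 genes in S. galili and 21 in S. carmeli had been turned into numbers. Of the 12310 genes in both files, 9884 (80.3%) had a symbol that is also in the RefSeq gene table of the S. galili v1.0 assembly, compared without regard to case. No coordinates are given, since the files name no genome build. A gene not listed in a file was treated as not listed, not as 0, because its contig may be unassembled or unnamed. Because names rest on matches to mouse, members of gene families and pseudogenes are uncertain.

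The ratio of each gene was log2((TPM in S. galili + 1)/(TPM in S. carmeli + 1)) minus the median log2 ratio of genes with at least 1 TPM in both libraries. The pseudocount of 1 understates the ratio of low genes. Folds with intervals are ratios of TPM without a pseudocount, divided by the median ratio. Genes counted as at least 4-fold apart needed 1 TPM and 10 expected counts in the higher library. With 1 library per species no test was made across genes and no p-value is given. Intervals of single values are exact 95% Poisson intervals, and those of ratios are exact conditional binomial intervals (Clopper-Pearson), both on expected counts rounded to whole numbers. They cover counting error only, and may be too narrow even for that, since reads without molecular identifiers are not independent molecules. At 10 counts the interval ran from 52.0% below to 83.9% above the value, and at 1000 counts from 6.10% below to 6.40% above.

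The 28 gene lists were fixed before the data were examined. A table of mouse names for human-style symbols was written after the files had been seen. The median of each list was placed among 10000 random lists of the same size, matched on 10 bins of mean log2 TPM, and its bootstrap interval came from 2000 draws of its members. A percentile is a description of these libraries.

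The genes named in the text follow a rule fixed before the data were examined. It takes the 10 most abundant genes of each library, and the 10 largest ratios in each direction among genes with at least 10 TPM and 50 expected counts in the higher library. From each list it takes the most abundant member and the largest ratio in each direction among members with at least 5 TPM. It also takes 12 genes whatever their values, of which Prl and Hba1 were not found under these names. Other list members and the contig names Lars2, Gm12913, Gm15662 and Mir5109 as a group were picked after their values were seen.

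The alternatives fixed in advance were pseudocounts of 0.1 and 5, no scaling, edgeR's trimmed mean of M-values (TMM) on rounded expected counts with counts scaled to CPM in place of TPM, no filter on low values, a minimum of 10 TPM, genes above 0 in both libraries, the most abundant transcript of each gene, and leaving out the 10 most abundant genes of each library. Added after seeing the data were genes whose longest contig was at least 500 bp in both libraries, and the non-coding match in place of the cDNA match. Ratios and list percentiles were tested on simulated data, a comparison of 2 libraries over 12310 genes with Poisson counts. Of 100 genes changed 8-fold, 99 were called at least 4-fold apart, as were 0 of 100 genes changed 2-fold and 0 of 12110 unchanged genes, and 3.5% of 200 random lists fell outside the central 95%. The simulation held no variation between animals, contig lengths or gene names, so it gives no rate of false calls for the real libraries. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.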

Results

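Placental RNA of 2 blind mole rat species, subterranean rodents of the genus Spalax, was sequenced. There was 1 library from the villous portion of Spalax galili placenta and 1 from that of Spalax carmeli placenta. The labels do not give the number of placentas or animals behind each library. The S. galili library held 49731326 expected counts on 157067 contigs, and the S. carmeli library held 52568965 on 236717 contigs. Contigs with a mouse gene name carried 77.3% of the transcript abundance (TPM) of the S. galili library and 59.7% of those of the S. carmeli library. They made up 13908 genes in S. galili and 13656 in S. carmeli, of which 12310 were listed in both files. With 1 library per species the difference between the libraries has no replicate check, and every interval below of a single gene covers counting error only. Bootstrap intervals of list medians cover the spread among list members only. A count of 100 has an exact 95% Poisson interval of 81.4 to 122, and a count of 10000 has one of 9805 to 10198.

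The most abundant named genes differed between the libraries. In S. galili they included Acta2, the smooth muscle actin gene, at 19520.2 TPM, the enteric-type actin gene Actg2 at 6813 TPM and the myosin light chain gene Myl9 at 5589 TPM. In S. carmeli they included the alpha globin gene Hba-a2 at 9242 TPM, the embryonic beta-type globin gene Hbb-y at 9098 TPM and Cts6, a cathepsin of the rodent placental family, at 6594 TPM. Hba-a2 and Cts6 were not listed in the S. galili file. Tmsb4x, which encodes the actin-binding peptide thymosin beta 4, was among the 10 most abundant genes of both libraries, with 9099 TPM in S. galili and 6359 TPM in S. carmeli. The ferritin heavy chain gene Fth1 stood at 7968 TPM in S. galili and 3464 TPM in S. carmeli, and Tpt1 at 5148 and 2370.4 TPM.

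Other abundant genes had names outside the lists of cell types. Lars2, Gm12913 and Gm15662 were the 3 most abundant named genes of S. galili, with 38052 TPM, 28366 TPM and 25624 TPM, against 10776 TPM, 7310.4 TPM and 6064 TPM in S. carmeli. Mir5109, at 7785 TPM, was listed in S. carmeli only. With Mir5105 added, these names held 13.9% of expected counts in S. galili and 3.32% in S. carmeli. No explanation was tested for this difference. In S. carmeli, Arpc4 reached 11658 TPM and Xrcc1 6113 TPM, against 154 TPM and 21.3 TPM in S. galili, and Lrrc58 was at 7336 TPM in S. galili against 42.3 TPM in S. carmeli. The names Lars2, Gm12913, Gm15662, Mir5109, Arpc4, Xrcc1 and Lrrc58 rest on matches to mouse that could not be checked, since no contig sequences were available. The 10 most abundant genes or unnamed components held 15.4% of the TPM in S. galili and 18.1% in S. carmeli. The 100 most abundant held 33.7% and 36.1%, and the 1000 most abundant 57.9% and 57.0%. Ranked by expected counts the order turned for the top 10 (23.4% and 22.003% of counts) and the top 100 (37.2% and 37.1%).

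Across the placentas of the 2 species, contractile, matrix and uterine genes were higher in the S. galili library, and trophoblast and steroid synthesis genes were higher in the S. carmeli library. Of 12059 genes that passed the minimum of 1 TPM and 10 expected counts in the higher library, 850 (7.05%) were at least 4-fold higher in S. galili and 692 (5.74%) at least 4-fold higher in S. carmeli. A further 7811 (64.8%) lay within 2-fold. Across the 12310 genes listed in both files, Pearson's r of log2(TPM + 1) was 0.708 and Spearman's rho was 0.690, as a description across genes, which are not independent replicates. The median log2 ratio of 0.14 over 11400 genes with at least 1 TPM in both libraries was subtracted from every ratio. With a pseudocount of 5 the counts were 457 and 405, and with TMM-scaled CPM in place of TPM they were 1328 and 992. Counting intervals of single genes do not cover such choices: of 91 named genes with a ratio, 28 moved by more than 1 on the log2 scale with TMM-scaled CPM.

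**Figure D1:**
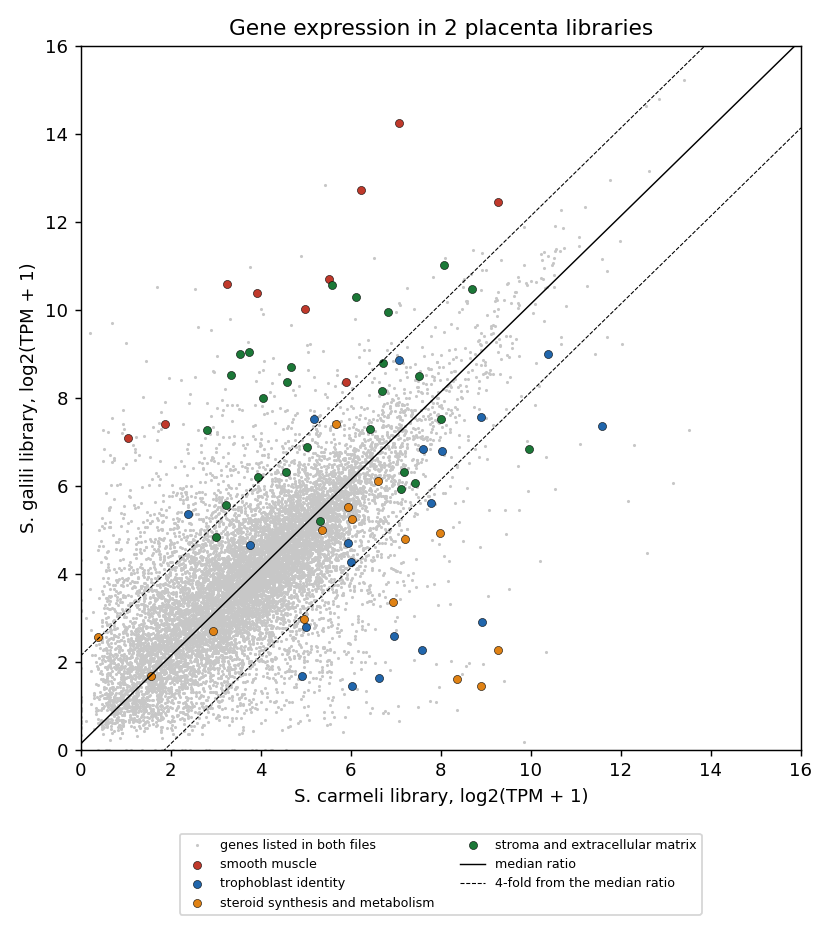
Each point is a gene listed in both files, with log2(TPM + 1) in the S. carmeli library on the x axis and in the S. galili library on the y axis. Coloured points are members of 4 gene lists, the solid line is the median ratio and the dashed lines lie 4-fold from it. The 10 smooth muscle genes lie above the upper dashed line.

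Among genes with at least 10 TPM and 50 expected counts in the higher library, the largest ratios toward S. galili included those of an immunoglobulin kappa variable gene and a neuropeptide precursor gene. Igkv16-104 was at 714 TPM against 0.16 TPM, a ratio of 4062 with a counting interval of 1389.9 to 19702 that rested on 3 counts in S. carmeli. Penk, which encodes proenkephalin, was at 826 TPM against 0.63 TPM (log2 ratio 8.85), and Npy, the neuropeptide Y gene, at 2011 TPM against 12.6 TPM (log2 ratio 7.08). H2-D1, a class I histocompatibility gene, was at 1424 TPM against 4.84 TPM, the latter on 12 counts and contigs of up to 399 bp. All class I genes together summed to 1441 TPM in S. galili and 611 TPM in S. carmeli, but to fewer expected counts in S. galili (49985 against 58096). Cd74, the invariant chain of class II molecules, was at 457 TPM against 1.73 TPM. Rpl12 and Gapdh were in the same group, with 1475 TPM against 2.23 TPM and 604 TPM against 1.02 TPM. The longest contig of these in S. carmeli was 279 bp for Rpl12 and 238 bp for Gapdh, with 10 and 3 expected counts, and the Gapdh ratio of 538 had a counting interval of 184 to 2611. The remaining genes of this group, Lrrc58, Cnn1 and Acta2, had log2 ratios of 7.27, 7.19 and 7.05.

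Toward S. carmeli the largest ratios included both the 17-alpha-hydroxylase gene Cyp17a1 and Star, whose product carries cholesterol into mitochondria. Cyp17a1 was at 475 TPM in S. carmeli and 1.75 TPM in S. galili, 299-fold higher with a counting interval of 225 to 405. Star was at 621 TPM and 3.81 TPM, 179-fold higher (157 to 205). Hbb-y was 152-fold higher (134 to 172), but on 264 counts and 1 contig of 273 bp in S. galili. Havcr1 stood at 328 TPM against 0.88 TPM, the latter on 10 counts and 1 contig of 486 bp. Chrnb4, a nicotinic acetylcholine receptor subunit gene, was at 489 TPM against 2.87 TPM. Tbc1d24 and BC051665 had log2 ratios of -7.98 and -8.27. The BC051665 value in S. galili rested on 9 counts and 1 contig of 227 bp, with a counting interval of the fold of 206 to 857. Akr1b8, at 235 TPM against 1.14 TPM, rested on 2 counts in S. galili, which gave a ratio of 227 with a counting interval of 62.8 to 1874. Rpl21, at 919 TPM against 0.14 TPM, rested on 4.93 counts in S. galili, and its ratio of 7219 had a counting interval of 3049.5 to 21923. Its log2 ratio of -9.79 was the largest of this group, but not with TMM-scaled CPM (-8.74, against -9.77 for BC051665) or a pseudocount of 5 (-7.63, against -8.00 for Xrcc1).

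Genes of smooth muscle were higher in the S. galili library without exception among those listed in both files. All 10 were at least 4-fold higher, with a median log2 ratio of 5.64 that lay at percentile 100 of 10000 random lists matched on mean expression. Acta2 (ENSMUSG00000035783) was 134-fold higher with a counting interval of 130.4 to 137, a log2 ratio of 7.05 that was 5.84 with TMM-scaled CPM, and Cnn1 (ENSMUSG00000001349), the calponin of smooth muscle, was 164-fold higher (149 to 179). Myh11, the smooth muscle myosin heavy chain gene, was at 1656 TPM against 44.5 TPM, and Des, which encodes the muscle intermediate filament desmin, at 1326 TPM against 14.1 TPM. The smallest ratio in the list was that of Smtn, at 2.34 on the log2 scale. Pln, the phospholamban gene, was listed in S. galili only, at 25.5 TPM.

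The decidua and uterine list was also higher in S. galili, with a median log2 ratio of 1.85 at percentile 100. Of 17 genes listed in both files, 8 were at least 4-fold higher in S. galili and 0 were at least 4-fold higher in S. carmeli. The progesterone receptor gene Pgr was at 83.6 TPM against 0.91 TPM, and the oestrogen receptor gene Esr1 at 39.4 TPM against 2.53 TPM, the latter on 8 counts. Hoxa10 and Hoxa11, homeobox genes of the developing and adult uterus, were at 212 TPM and 52.9 TPM against 10.9 TPM and 7.43 TPM. Wnt4 had the largest ratio the other way, at 1.86 TPM against 5 TPM (log2 ratio -1.21). Beside these values stand the smooth muscle genes above, which moved in the same direction, and 3 genes of the list are also in another list.

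Stromal and matrix genes followed the same direction, with 13 of 27 at least 4-fold higher in S. galili, 1 at least 4-fold higher in S. carmeli and a median log2 ratio of 1.94 (percentile 100). The collagen gene Col6a2 was 43.3-fold higher (41.2 to 45.5), Col1a1 was at 1249 TPM against 68.7 TPM, and the decorin gene Dcn at 1514 TPM against 46.8 TPM. Sparc, a matrix glycoprotein gene, was the most abundant member, at 2089.9 TPM against 268 TPM. Of the 6 genes higher in S. carmeli, Fn1, the fibronectin gene, was the only member at least 4-fold higher, at 113 TPM against 995 TPM in S. carmeli (log2 ratio -3.26).

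Trophoblast genes were higher in the S. carmeli library. Of 19 listed in both files, 9 were at least 4-fold higher in S. carmeli and 2 at least 4-fold higher in S. galili, with a median log2 ratio of -1.87 at percentile 0 (-2.95 with TMM-scaled CPM). Cited1, a transcriptional co-regulator gene of the placenta, was at 480.2 TPM in S. carmeli against 6.53 TPM in S. galili, an 80.8-fold difference (69.5 to 94.9). Pparg, a nuclear receptor gene needed for placental development, was 54.6-fold higher (47.8 to 62.8), and the transcription factor genes Tfap2c and Gata3 had log2 ratios of -5.12 and -4.51. Krt18, a keratin of simple epithelia, was the most abundant member, at 3045 TPM against 164 TPM. Tfap2a, Hand1, Gcm1, Plac1, Cdx2 and Ovol1 were listed in S. carmeli only, at 158 TPM, 113 TPM, 26.4 TPM, 19.8 TPM, 18.98 TPM and 2.27 TPM, and Eomes was listed in S. galili only, at 2.67 TPM. Elf5, a transcription factor gene of trophoblast stem cells, and Krt7 were higher in S. galili, at 39.9 TPM against 4.2 TPM and 183 TPM against 35.4 TPM.

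**Figure D2:**
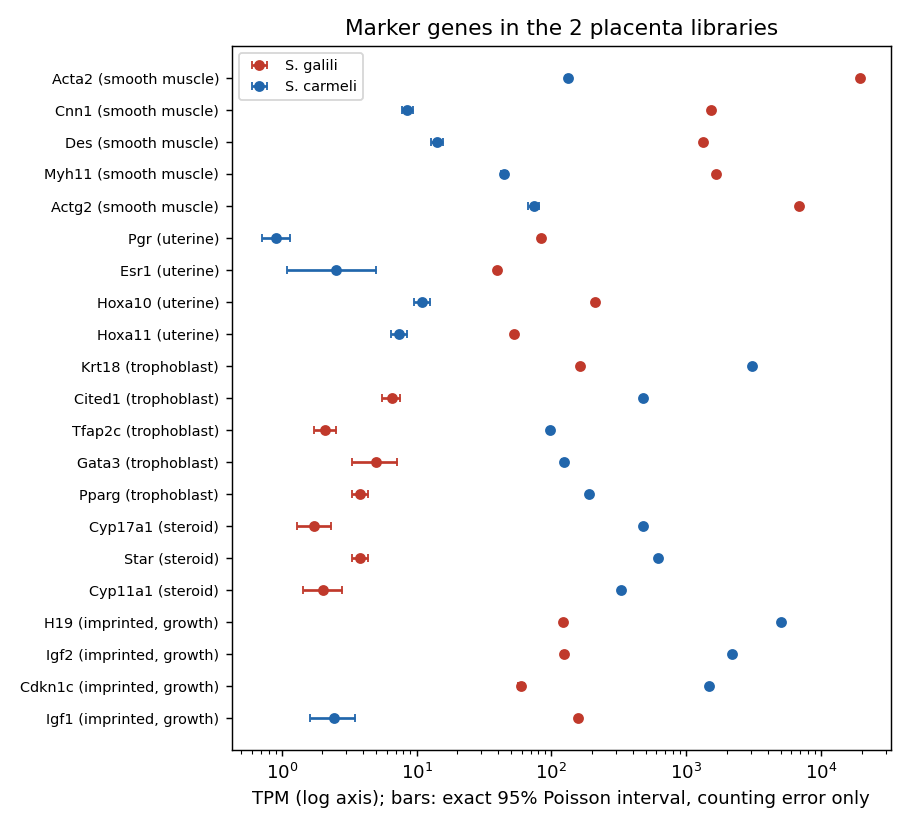
Each row is a gene, with its TPM in the S. galili library in red and in the S. carmeli library in blue on a log axis. The genes are a selection, in part picked after their values were seen, and do not stand for their whole lists. Members that lay opposite to their list median, such as Elf5, Krt7, Wnt4 and Hsd11b2, are not shown. Bars are exact 95% Poisson intervals for counting error only. Acta2 lies at 19520.2 and 133 TPM, and Cyp17a1 at 1.75 and 475 TPM.

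Genes of steroid synthesis were higher in S. carmeli, with 7 of 15 at least 4-fold higher there, 1 at least 4-fold higher in S. galili and a median log2 ratio of -0.91 (percentile 0.17). The median was -2.04 with TMM-scaled CPM and -1.51 with contigs of at least 500 bp. The trophoblast list was also higher in S. carmeli (-1.87). Beside Cyp17a1 and Star, Cyp11a1, whose product cleaves the cholesterol side chain, was 176-fold higher (129 to 248), and Fdxr, its electron donor's reductase gene, 14.3-fold higher (13.0 to 15.7). The aromatase gene Cyp19a1 was at 2.21 TPM in S. galili and 1.97 TPM in S. carmeli, with a ratio interval of 0.501 to 1.87, but its log2 ratio of -0.02 was -2.04 with TMM-scaled CPM, on 11 and 180 counts and longest contigs of 410 bp and 2456 bp. Hsd11b2, which inactivates glucocorticoids, was higher in S. galili, at 167 TPM against 49.8 TPM.

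Of 39 prolactin family and pregnancy hormone genes, 9 were listed in either file and 5 in both, with 3 of the 5 higher in S. galili. None of the 5 is a prolactin family gene, and their median log2 ratio of 1.68 (percentile 99.5) had a bootstrap interval of -3.40 to 3.66. It was 0.67 with a pseudocount of 5 and 2.53 with one of 0.1. The activin subunit gene Inhbb was at 56.8 TPM in S. galili against 3.16 TPM, and the follistatin gene Fst at 115 TPM against 17.7 TPM. The adrenomedullin gene Adm was 12.1-fold higher in S. carmeli (10.6 to 13.8). Prl5a1, at 269.7 TPM, and the pregnancy-specific glycoprotein gene Psg16, at 33.1 TPM, were listed in S. carmeli only.

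Imprinted genes went both ways, with 10 of 27 at least 4-fold higher in S. carmeli, 3 at least 4-fold higher in S. galili and a median log2 ratio of 0.14 (percentile 72.2). That median turned to -0.08 with TMM-scaled CPM. The non-coding RNA H19 was at 5046 TPM in S. carmeli against 122 TPM in S. galili, and the fetal growth factor gene Igf2 at 2176 TPM against 123 TPM. Phlda2 and Cdkn1c, which restrain placental and cell growth, had log2 ratios of -5.50 and -4.75, and the retrotransposon-derived Peg10 had one of -2.32. Dcn and the tetraspanin gene Cd81, at log2 ratios of 4.85 and 3.11, were higher in S. galili.

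In the insulin-like growth factor list, the 2 ligand genes lay on opposite sides. Igf1 was at 156 TPM in S. galili against 2.43 TPM in S. carmeli, whereas Igf2 was 19.4-fold higher in S. carmeli (18.8 to 20.1). The list median was 0.93 (percentile 99.9), with 3 of 22 genes at least 4-fold higher in S. galili and 2 in S. carmeli. The stromal (1.94), smooth muscle (5.64) and uterine (1.85) lists were also higher in S. galili, and 9 genes of the list are also in other lists. Igfbp5, a binding protein gene, was at 1100.1 TPM against 136 TPM.

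Hypoxia response genes as a list were higher in the S. carmeli library, as were trophoblast genes (median -1.87), whereas smooth muscle (5.64) and uterine genes (1.85) were higher in S. galili. The median log2 ratio was -0.72 (percentile 0), with 8 of 41 genes at least 4-fold higher in S. carmeli and 4 in S. galili. The glucose transporter genes Slc2a3 and Slc2a1 were 20.7-fold (19.2 to 22.5) and 17.4-fold (16.9 to 18.0) higher in S. carmeli, and the angiogenic factor gene Vegfa 7.32-fold higher (6.85 to 7.83). Hif1a, which encodes the oxygen-regulated subunit of hypoxia-inducible factor 1, was at 78.0 TPM in S. galili and 48.2 TPM in S. carmeli (log2 ratio 0.55), and its sign turned with TMM-scaled CPM (-0.14). Epas1, a related factor gene, was 3.02-fold higher in S. carmeli (2.95 to 3.09). The glycolytic gene Aldoa, the most abundant member, was at 590.2 TPM and 472 TPM.

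The embryonic globin gene Hbb-y was higher in S. carmeli, and the direction of Hbb-b1 depended on the unit. The Hbb-y value in S. galili rested on 264 counts and 1 contig of 273 bp, against a contig of 706 bp in S. carmeli. Beside Hba-a2 and Hbb-y, Hbb-b1 was at 2753 TPM in S. carmeli against 514 TPM in S. galili, a log2 ratio of -2.55 that became 1.22 with TMM-scaled CPM, which make no length correction. Its longest contig was 2650 bp in S. galili and 415 bp in S. carmeli. Over 4 globins listed in both files the median log2 ratio was -1.21 (percentile 1.79, bootstrap interval -7.22 to 1.23), or 0.74 with TMM-scaled CPM, and Cygb, the cytoglobin gene, was at 6.88 TPM against 2.05 TPM. Of 9 erythroid genes, 2 were at least 4-fold higher in S. carmeli and 0 in S. galili, with a median of -0.54 (percentile 7.94), or -1.10 with TMM-scaled CPM and -0.84 with contigs of at least 500 bp. Alas2, the erythroid haem synthesis gene, was at 66.4 TPM in S. carmeli against 12.3 TPM, and Tmcc2 at 6.75 TPM against 19.7 TPM.

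The lists tied to oxidative stress, longevity and cancer resistance in these animals had medians near 0. Of 32 antioxidant genes, 2 were at least 4-fold higher in each library, with a median log2 ratio of 0.20 (percentile 86.2), and the metallothionein gene Mt1 was at 1089.8 TPM in S. carmeli against 229 TPM. Ftl1, the ferritin light chain gene, was at 121 TPM in S. galili against 1.25 TPM on 14 counts. The p53 and DNA repair list had a median of -0.05 (percentile 37.7), with 0 of 34 genes at least 4-fold higher in S. galili and 2 in S. carmeli. Xrcc1 was its most abundant member and had its largest ratio, 315-fold higher in S. carmeli (299 to 332). The name Xrcc1 could not be checked by sequence, and its longest contig was 3568 bp in S. carmeli and 2071 bp in S. galili. Trp53, the p53 gene, was at 36.0 TPM in S. galili and 21.7 TPM in S. carmeli, and Casp3, an executioner caspase gene, at 22.9 TPM and 5.34 TPM. The hyaluronan and heparanase list had a median of -0.04 (percentile 41.1), with 1 of 17 genes at least 4-fold higher in each library. Hpse, the heparanase gene, was at 12.1 TPM and 15.1 TPM. Sdc1 was at 67.0 TPM and 133 TPM, and the versican gene Vcan, at 40.4 TPM against 5.05 TPM, and Gpc3, at 3.05 TPM against 14.6 TPM, had the largest ratios in each direction.

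Cell cycle genes were higher in S. carmeli, with 10 of 32 at least 4-fold higher there, 1 in S. galili and a median log2 ratio of -1.51 (percentile 0), or -2.05 with TMM-scaled CPM. The trophoblast list was also higher in S. carmeli (-1.87), and the smooth muscle (5.64) and uterine (1.85) lists were higher in S. galili. The cyclin gene Ccnb1 was at 32.0 TPM against 1 TPM, Ccne1 at 51.4 TPM against 3.28 TPM, and Cdkn1c, a cell cycle inhibitor gene, at 1484 TPM against 59.5 TPM. Of the 6 genes higher in S. galili, Ccnd2 was the only member at least 4-fold higher, at 17.9 TPM in S. galili against 2.03 TPM.

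Endothelial genes were higher in S. carmeli, with a median log2 ratio of -0.99 (percentile 0.09) and 4 of 16 genes at least 4-fold higher there against 1 in S. galili, the same direction as the trophoblast list (-1.87). Pecam1 was at 304 TPM against 72.5 TPM and Egfl7 at 99.8 TPM against 8.71 TPM, whereas the von Willebrand factor gene Vwf was at 76.0 TPM in S. galili against 5.88 TPM. The angiogenesis list had a median of -0.24 (percentile 12.8), or -0.76 with TMM-scaled CPM, with 7 of 29 genes at least 4-fold higher in S. carmeli and 0 in S. galili. Nrp2, a co-receptor gene, was at 69.4 TPM in S. galili and 22.5 TPM in S. carmeli.

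Leukocyte genes had a median log2 ratio of 0.24 (percentile 75.9) over 10 genes, which turned to -1.06 over the 6 genes with contigs of at least 500 bp in both libraries, and a further 7 were listed in S. galili only. Lcp1 was at 84.2 TPM in S. carmeli against 9.41 TPM, opposite to Cd74. The interferon and MHC list had a median of 0.42 (percentile 92.3), or 0.81 with TMM-scaled CPM, with 4 of 16 genes at least 4-fold higher in S. galili and 2 in S. carmeli. Ifitm2 was at 607 TPM in S. galili against 117 TPM and the tapasin gene Tapbp at 139 TPM against 13.2 TPM, whereas the interferon-induced Rsad2 was at 179.6 TPM in S. carmeli against 0.95 TPM.

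Among proteases and inhibitors, 7 of 20 genes were at least 4-fold higher in S. galili and 5 in S. carmeli, with a median log2 ratio of 0.84 (percentile 99.8). The bootstrap interval of this median was -0.60 to 2.68, and 8 genes of the list are also in other lists. A further 3 members were listed in S. galili only and 2 in S. carmeli only, and they entered neither these counts nor the median. Among them was Cts6, the most abundant member, at 6594 TPM in S. carmeli and not listed in S. galili. The median was 0.42 with contigs of at least 500 bp and 1.44 with TMM-scaled CPM. Serpinf1, at 145 TPM against 0.88 TPM, rested on 2 counts in S. carmeli, which gave a ratio of 150.1 with a counting interval of 41.5 to 1239. Serpine1, the plasminogen activator inhibitor 1 gene, was 30.6-fold higher in S. carmeli (28.5 to 32.8). Nutrient transporter genes had a median of -0.32 (percentile 5.35), or -0.57 with TMM-scaled CPM, with 9 of 33 at least 4-fold higher in S. carmeli and 4 in S. galili. Slc2a8 was at 4535 TPM in S. carmeli against 49.3 TPM, and the amino acid transporter gene Slc38a1 at 42.9 TPM in S. galili against 0.55 TPM on 4 counts. The name Slc2a8 could not be checked by sequence. Genes of yolk sac and liver-type secreted proteins had a median of -0.07 (percentile 35.2) over 19 genes, with the transferrin gene Trf at 963 TPM in S. galili against 15.5 TPM and the apolipoprotein gene Apob at 13.2 TPM in S. carmeli against 0.35 TPM.

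The remaining lists describe housekeeping functions and RNA quality. Ribosomal protein genes had a median log2 ratio of 0.51 (percentile 99.9) over 62 genes, of which 52 were higher in S. galili, 5 were at least 4-fold higher in S. galili and 3 in S. carmeli, and Rps29 was the most abundant, at 3241 TPM and 2133 TPM. Nuclear oxidative phosphorylation genes had a median of -0.39 (percentile 4.64) with 0 of 22 at least 4-fold apart, and Uqcrh was at 463 TPM in S. galili and 490.2 TPM in S. carmeli. Cycs, the cytochrome c gene, was at 48.5 TPM and 138 TPM, and Ndufa4 at 544 TPM and 288 TPM. Housekeeping genes had a median of -0.22 (percentile 20.5) over 16 genes, which turned to 0.35 with the non-coding match of a contig kept, with the elongation factor gene Eef1a1 at 3016 TPM and 4047 TPM (log2 ratio -0.56, which turned to 0.57 with TMM-scaled CPM) and the transferrin receptor gene Tfrc at 8.86 TPM and 41.3 TPM. Stress and dissociation genes had a median of 0.26 (percentile 84.0) over 22 genes, with Hspb1 at 1182 TPM and 379.7 TPM, Klf4 at 129.5 TPM and 16.9 TPM, and the immediate early gene Fos at 5.04 TPM and 67.4 TPM. The mitochondrial list had a median of -0.64 (percentile 13.5) over 3 genes, which ranged from -1.08 to -0.12 over the settings run, with mt-Co1 at 598 TPM and 4155 TPM and mt-Nd1 at 6.9 TPM and 3.2 TPM. Contigs of up to 16454 bp in S. galili and 16405 bp in S. carmeli that carried mitochondrial names held 4312 TPM and 4136 TPM, under different gene names. The contig of 16405 bp was listed as mt-Co1 and held most of the mt-Co1 value of S. carmeli. In S. galili the longest mt-Co1 contig was 1700 bp, so the mt-Co1 values of the 2 libraries are of unlike contigs. Of the replication-dependent histones only Hist1h1c was listed in both files, at 132 TPM and 143 TPM, a log2 ratio of -0.26 (percentile 37.3).

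**Figure D3:**
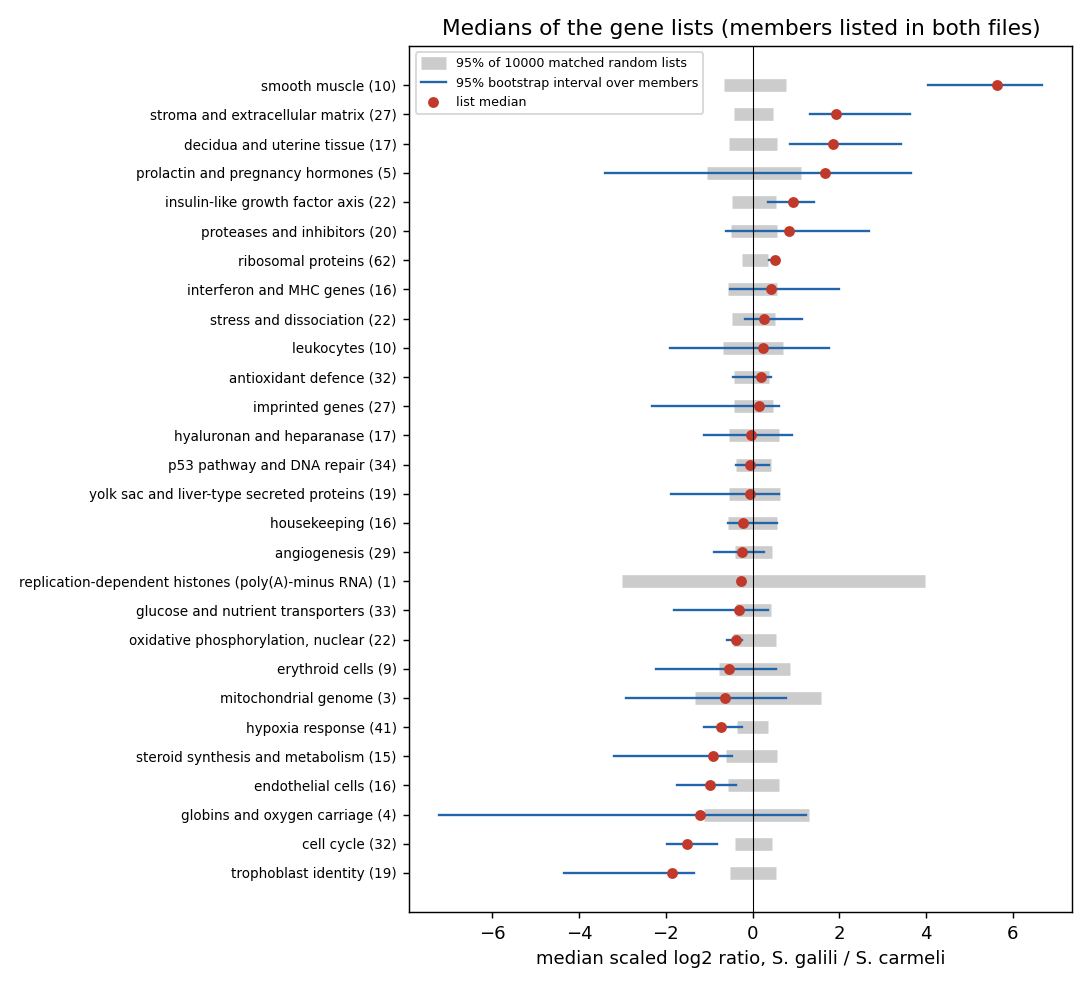
Each row is a gene list with its number of genes listed in both files, and the x axis is the scaled log2 ratio of S. galili over S. carmeli. Red points are list medians, blue lines are 95% bootstrap intervals over members and grey bars span 95% of 10000 matched random lists. Smooth muscle lies highest at 5.64 and trophoblast identity lowest at -1.87.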

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

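The tests of scaling, of the share of trophoblast RNA, of uterine tissue, of the ribosomal protein family as a whole and of short fragments among ribosomal protein genes were chosen after the results were seen. The tests of contig length on the smooth muscle and trophoblast lists and of pseudogene names were written before theirs.

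Contigs with no gene name entered no ratio, and they are given here because they held reads at all, which any share above 0 would meet. They held 22.7% of TPM in S. galili and 40.3% in S. carmeli. The most abundant unnamed component held 0.479% of TPM in S. galili and 8.81% in S. carmeli, where its longest contig was 1682 bp. No explanation was tested for these values.

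Smooth muscle and uterine genes were higher, and trophoblast genes lower, in the library labelled S. galili placenta. All 19 trophoblast genes had a longest contig of at least 500 bp in both libraries (median -1.87), as did 9 smooth muscle genes, whose median was still 5.39. The pattern therefore does not rest on genes named only on short fragments. Reads on short fragments of these genes are not excluded, since TPM was summed over all contigs of a gene. A scaling factor moves every list alike, so it would not by itself set the smooth muscle and trophoblast lists apart. The gap from the lower bootstrap bound of the smooth muscle median to the upper trophoblast bound was 5.40 on the log2 scale. That gap is the same under any scaling factor, so its size restates the pattern and adds no separate evidence about scaling. A lower share of trophoblast RNA alone would raise other cell types alike, but the endothelial median was -0.99. That value bears only on a drop in trophoblast RNA that leaves the proportions of other cell types unchanged. Uterine wall tissue in the S. galili sample stays open, although the protocol took the villous portion. The 16 decidua and uterine genes outside the smooth muscle list had a median of 1.59 (bootstrap interval 0.87 to 3.38), but these genes are part of the pattern, so their median restates it and is no test of its source. A difference between the placentas of the 2 species stays open and untested with 1 library per species, as does gestational stage, which the labels do not give.

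Of 62 ribosomal protein genes in both files, 5 were at least 4-fold higher in S. galili and 3 at least 4-fold higher in S. carmeli, with Rpl12 and Rpl21 the furthest apart (log2 ratios 8.70 and -9.79). The family as a whole was higher in S. galili, with 52 of the 62 genes higher there, but its summed TPM differed by 0.51 on the log2 scale, which is too small to account for the 8 genes, 3 of which lay on the other side. A gene name on a short fragment in the lower library was not decided: 1 of the 8 genes, Rpl12, had a contig there under 0.5 times the length of that in the higher library (12.5%), against 1 of 47 genes within 2-fold (2.13%). In 6 of the 8, Rpl21 among them, the contig in the lower library was the longer. Adding pseudogene names of the same protein left 100% of the 8 genes at least 4-fold apart, but none of them had such a name listed, so that test was void and the cause stays open.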

How the results depend on the processing

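The contig length minimum and the choice of the non-coding match were added after the data were seen, and the other alternatives were fixed before. No paired analysis was possible because each species has 1 library, and leaving out a library was not possible for the same reason.

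With a pseudocount of 5 the genes at least 4-fold higher numbered 457 in S. galili and 405 in S. carmeli, against 850 and 692, since a larger pseudocount shrinks the ratios of low genes. With TMM-scaled CPM the S. galili count was 1328, of which 779 were among the 850, and the S. carmeli count was 992, of which 607 were among the 692. The median change of the log2 ratio over the counted genes was 0.03, so a shared shift of all ratios does not account for these counts. CPM also make no length correction between contigs, but its effect on the counts was not tested. The other settings kept both counts within 1.5 times, between 713 and 1120 in S. galili and between 568 and 872 in S. carmeli. Without scaling every log2 ratio was higher by 0.14 and S. galili held 62.3% of the calls, against 55.1%.

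Pearson's r was 0.693 with a pseudocount of 0.1 and 0.722 with 5, against 0.708. The 10 genes or unnamed components with the most expected counts held 23.4% of counts in S. galili and 22.003% in S. carmeli, and the 10 most abundant contigs 14.6% and 16.6% of TPM, against 15.4% and 18.1% of TPM for the 10 most abundant genes or unnamed components. The smooth muscle median was 6.93 with TMM-scaled CPM, against 5.64 (the causes of these shifts were not tested), and ranged from 4.84 to 6.93 over all settings. The medians of the uterine (1.28 to 2.54), stromal (1.81 to 2.31) and trophoblast (-2.95 to -1.68) lists kept their sign in every setting run. The steroid median was -2.04 and the cell cycle median -2.05 with TMM-scaled CPM, against -0.91 and -1.51. The protease median ranged from 0.42 to 1.44 and the prolactin and hormone median from 0.67 to 2.53.

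The globin median turned from -1.21 to 0.74 with TMM-scaled CPM and to 0.69 with contigs of at least 500 bp, which left 2 of its 4 genes. Medians inside the range of random lists turned too: leukocytes to -1.06 with contigs of at least 500 bp, housekeeping to 0.35 with the non-coding match, imprinted genes to -0.08 with TMM-scaled CPM, and without scaling p53 and repair genes to 0.08, hyaluronan genes to 0.09 and yolk sac genes to 0.07 (also 0.07 with contigs of at least 500 bp). Hbb-b1 turned from -2.55 to 1.22 with TMM-scaled CPM, which make no length correction between contigs of 2650 bp and 415 bp. Among 91 named genes with a ratio, 3 turned sign with TMM-scaled CPM (Hbb-b1, Eef1a1 and Hif1a), 1 without scaling and 1 with a pseudocount of 0.1 (Cyp19a1 in both), and 0 with a pseudocount of 5. Of the same 91, the log2 ratio moved by more than 1 in 28 with TMM-scaled CPM, 17 with a pseudocount of 5, 5 with one of 0.1 and 0 without scaling. Depth limits genes with few counts: a count of 10 has an interval of 4.80 to 18.4.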

Other observations

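The genes and families in this part were picked after their values were seen, and no explanation was tested for them.

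Immunoglobulin genes, which plasma cells and B cells express, summed to 1149 TPM over 10 genes in S. galili and to 3.26 TPM over 5 genes in S. carmeli. Class II histocompatibility genes summed to 352 TPM and 50.8 TPM, and class I genes to 1441 TPM and 611 TPM, with 49985 expected counts of class I in S. galili and 58096 in S. carmeli. Emx2, a homeobox gene of the urogenital tract, was at 140.3 TPM in S. galili and 1.66 TPM in S. carmeli, 76.9-fold higher (53.2 to 116). Synb, a syncytin gene of the fused trophoblast layer in mouse, was listed in S. carmeli only, at 151 TPM. The beta-type globin genes summed to 1190.1 TPM in S. galili and 11851 TPM in S. carmeli.

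Genes listed in a single file numbered 1598 in S. galili and 1346 in S. carmeli, of which 290 and 186 reached 10 TPM. The names Lars2, Gm12913, Gm15662, Mir5105 and Mir5109 together held 13.9% of expected counts in S. galili and 3.32% in S. carmeli. The mitochondrial contigs of up to 16454 bp and 16405 bp held 4.92% of expected counts in S. galili and 5.10% in S. carmeli.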
